A study of Mus musculus with 4 samples.

How the data were processed

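RNA was sequenced from male C57BL/6 mouse pneumocytes in 4 libraries, 2 labelled Kras;Rank+/+ and 2 labelled Kras;Rankfl/fl. Per the labels' protocols, total RNA was purified on a column kit, poly-A RNA was selected with poly-T, cDNA was made with dUTP, which marks the strand, and libraries followed an Illumina TruSeq protocol. The deposited values are TPM per gene symbol with 2 decimals, and their totals per library are equal to within rounding. The submitters' processing notes name the mouse assembly mm10 and the tools STAR 2.5.0a, HTSeq, RSEM 1.2.25 and DESeq2 1.10.1, without saying which step each served. The gene annotation, the use of strand in counting, the treatment of reads that match several genes and any filter on genes are not given in the sources used here.

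TPM corrects each gene for its length and each library for its total, so it keeps no read depth. The precision of low values is therefore unknown, no count model was applied, and a value of 0 is reported only as listed at 0. Because the values of a library add up to a fixed total, more RNA from abundant genes lowers all others. Poly-A selection leaves out most histone messages, and genes shorter than a read or inside another gene's exon can take reads of their host. The files list 0 genes under the symbols of the mitochondrial genome, so the share of mitochondrial RNA could not be used as a sign of RNA quality.

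Values were compared as log2(TPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a variance trend), for genes with a mean of at least 1 TPM over the 4 libraries, which left 14535 of 24411. The model had a term for the genotype label and 2 residual degrees of freedom, to which the variance prior added 3.00. Log2 fold changes are the libraries labelled Rankfl/fl minus those labelled Rank+/+, and the pseudocount of 1 makes them understate the change of low genes. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. In the text, TPM values of single libraries are given as replicates 1 and 2 of the libraries labelled Rank+/+, then replicates 1 and 2 of those labelled Rankfl/fl, and means carry the SD over 2 libraries.

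Gene lists were tested against all other tested genes with camera in limma, with a preset correlation of 0.01 between genes. The 36 lists, 7 of them primary (oxidative phosphorylation, TCA cycle, glycolysis, fatty acid oxidation, NF-kB target genes, cell cycle and alveolar type II markers), were fixed before the data were examined, as were the main model, the alternatives and the naming rule. The other lists hold markers of further lung cell types, signalling and stress pathways, ribosomal proteins and signs of RNA quality. At least 5 tested members were required, which 32 lists had, and Benjamini-Hochberg adjustment ran over these 32. The value of a list is the median log2 fold change of its members. A correlation estimated from the residuals of each list was the alternative to the preset value, and 0 of the 15 called lists held with it. That alternative also judges its statistic on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. A call lost with it therefore does not by itself point to correlation between genes. Members were also adjusted over the list alone. Some genes stand on more than 1 list.

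The naming rule took Tnfrsf11a, Kras and Tnfsf11 always, and the 12 genes with the largest fold change in each direction past the threshold with groups that did not overlap, filled from the smallest p at a mean of at least 5 TPM where fewer passed. It left out pseudogenes, microRNAs, small nucleolar RNAs, ribosomal RNAs and predicted genes. Since no gene that the rule allows passed, all 24 places were filled in this way. From each list, up to 4 members of smallest p and up to 2 of highest mean TPM were eligible as examples. Positions, strands and gene types were taken by symbol from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. It matched 23334 of the 24411 symbols and 13963 of the tested genes.

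The limma step was tested on simulated data for the same comparison of 2 against 2 libraries over 14535 genes, with the spread drawn from the variance prior of the real fit and 200 genes changed in each of 5 runs. It recovered 2.09% of genes changed by 1 on the log2 scale, 67.2% of those changed by 2 and 95.2% of those changed by 4, and 36 of 582 calls were false. The changed genes were drawn only from the more highly expressed ones. Genes were simulated independently, with no library that stands apart, so these rates may not hold for low genes or for the real libraries.

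The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, a variance prior without the trend, the replicate number as a block, an estimated correlation in the set test, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other group. Leaving out genes named as microRNAs or small nucleolar RNAs was added after seeing the data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Other splits of the samples were not used as a test, since groups of 2 allow too few. No file was left out.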

Results

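Gene expression was measured by RNA sequencing in 4 libraries of primary mouse pneumocytes, the epithelial cells of the lung alveolus, from male C57BL/6 animals. Per the labels, 2 libraries came from Kras;Rank+/+ cells and 2 from Kras;Rankfl/fl cells, and the cells had been exposed to Rankl in culture. Rank is the receptor encoded by Tnfrsf11a, and Rankl is its ligand, encoded by Tnfsf11. A floxed (fl) allele carries recognition sites at which a recombinase can remove part of a gene. The labels do not give the Kras allele, the floxed part of Tnfrsf11a, how recombination was brought about, or the dose and duration of Rankl. The comparison asks how the transcriptome of Rankl-treated pneumocytes differs with the Rank genotype. Values are TPM, each gene's length-corrected share of a library's transcripts on a fixed scale, for 24411 gene symbols, and the read depth of each library is unknown, so no counting interval could be given. Between 19019 and 19718 genes had a value above 0 in a library, and 14535 genes with a mean of at least 1 TPM were tested. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

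The library labelled Rank+/+ replicate 1 stood apart from the other 3 libraries. The first principal component of log2(TPM + 1) took 67.3% of the variance and placed it at −61.9, with Rank+/+ replicate 2 at 0.647 and the libraries labelled Rankfl/fl at 24.4 and 36.9. Across genes, which are not independent replicates, Pearson's r between the Rank+/+ libraries was 0.957, while Rank+/+ replicate 2 reached 0.977 with Rankfl/fl replicate 1 and 0.968 with Rankfl/fl replicate 2. The libraries labelled Rankfl/fl had r = 0.975 with each other. The most abundant transcripts differed as well. They were Ftl1, the ferritin light chain, at 9611 TPM in Rank+/+ replicate 1, Spp1 (osteopontin) at 9644 TPM in Rank+/+ replicate 2, Sparc at 8082 TPM in Rankfl/fl replicate 1 and Lyz2 (lysozyme) at 15408 TPM in Rankfl/fl replicate 2. The 10 most abundant genes took 6.14% to 9.16% of a library.

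**Figure D1:**
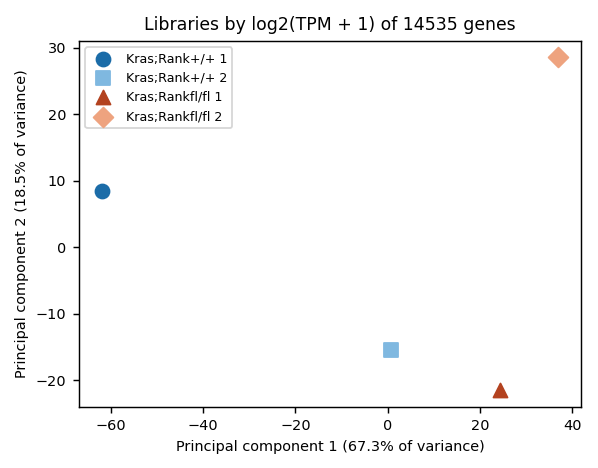
Each point is 1 library, placed by its scores on the first (x axis, 67.3% of variance) and second (y axis, 18.5% of variance) principal components of log2(TPM + 1) over 14535 genes. The library labelled Rank+/+ replicate 1 lies at −61.9 on the first axis, and the other 3 libraries lie between 0.647 and 36.9.

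Tnfrsf11a, the gene of the floxed allele, was not lower in both libraries labelled Rankfl/fl. Its level was 2.27 and 2.45 TPM in the libraries labelled Rank+/+ and 1.38 and 2.60 TPM in those labelled Rankfl/fl, so that Rankfl/fl replicate 2 lay above both Rank+/+ libraries. The log2 fold change was −0.20 ± 0.30 (SE), with a 95% confidence interval from −0.96 to 0.57 and a limma adjusted p of 0.774, and without Rankfl/fl replicate 1 it was 0.10. The gene lies at chr1:105780718–105847981 on the plus strand (mm10). A value summed over a whole gene need not fall when only some exons are removed, so it tests the genotype labels weakly, and the groups are called here by their labels. Kras (chr6:145216699–145250239, minus strand) was at 38.8 and 34.8 TPM in the libraries labelled Rank+/+ and at 42.0 and 34.3 TPM in those labelled Rankfl/fl. Its log2 fold change of 0.04 ± 0.18 (SE; limma adjusted p = 0.925) changed sign with median-of-ratios scaling (−0.03) and with quantile normalization (−0.02), and also without Rank+/+ replicate 2 (−0.03) or Rankfl/fl replicate 1 (−0.10). The ligand gene Tnfsf11 was under the filter for testing, at 0.53 and 0.78 TPM against 1.02 and 1.13 TPM.

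Between the genotype labels, 2 genes passed the threshold, 1 lower and 1 higher in the libraries labelled Rankfl/fl. Serpina3h, a member of the Serpina3 family of secreted protease inhibitors, was at 108.9 and 151.2 TPM in the libraries labelled Rank+/+ and at 0.80 and 1.09 TPM in those labelled Rankfl/fl. Its log2 fold change was −6.06 ± 0.23 (SE; limma adjusted p = 0.0222). Serpina3h lies at chr12:104247905–104253669 on the plus strand, and the annotation calls it a transcribed pseudogene of a family of near-identical paralogs, so the division of reads among them is uncertain. Mir3098 was listed at 0 in both libraries labelled Rank+/+ and at 18.9 and 20.2 TPM in those labelled Rankfl/fl (limma adjusted p = 0.0361). This short gene (chr6:125195792–125195878, plus strand) lies inside an exon of Mrpl51 on the same strand, so reads of the 2 genes cannot be told apart. Mrpl51 itself was at 67.3 and 67.9 TPM against 59.1 and 62.2 TPM (log2 fold change −0.15 ± 0.15 SE; limma adjusted p = 0.654). Both genes fall outside the naming rule and were named after their values were seen. Both calls were lost without Rank+/+ replicate 1 (log2 fold change −6.29 and limma adjusted p = 0.161 for Serpina3h, 4.36 and 0.234 for Mir3098), without Rankfl/fl replicate 1 (−5.95 and 4.40; 0.313 for each) and without Rankfl/fl replicate 2 (−6.17 and 4.31; 0.968 for each), so that the fold changes stayed near those with all libraries (−6.06 and 4.36) while p rose. By contrast, more genes passed without Rank+/+ replicate 2, where the library that stood apart was the only Rank+/+ library left. With no filter on low values, limma called 0 genes, with 1152 higher and 583 lower at an unadjusted p under 0.05.

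At an unadjusted p under 0.05, 969 genes were higher and 485 lower in the libraries labelled Rankfl/fl, where 727 in all are expected by chance. This split depended on scaling, with 701 higher and 675 lower after median-of-ratios scaling and 673 higher and 723 lower after quantile normalization. Both Rankfl/fl values lay above both Rank+/+ values for 4471 genes and below for 2663, together 49.1% of the genes against 33.3% by chance. Genes vary together and Rank+/+ replicate 1 stood apart, so the spread of these chance values is unknown. Neither excess can be tied to the genotype.

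Among the genes with the smallest p, none of which passed the threshold, 12 higher in the libraries labelled Rankfl/fl are given here. Lamc2, a chain of the basement membrane protein laminin-332, was at 51.2 ± 3.20 TPM (SD, n = 2) in the libraries labelled Rank+/+ and at 120.1 ± 5.02 TPM in those labelled Rankfl/fl. Itga3, the alpha chain of an integrin that binds laminin, was at 127.1 ± 2.79 against 264.8 ± 2.02 TPM. Lad1, which encodes the basement membrane zone protein ladinin, was at 9.21 ± 2.76 against 30.9 ± 0.891 TPM. Rab25, a small GTPase of epithelial cells, was at 7.47 ± 0.354 against 19.1 ± 2.44 TPM. Prss8, the membrane protease prostasin, was at 8.07 ± 1.07 against 20.5 ± 1.69 TPM. The log2 fold changes of these 5 genes ran from 1.05 for Itga3 to 1.67 for Lad1, with limma adjusted p-values from 0.312 to 0.355. Serpinb2, a plasminogen activator inhibitor at chr1:107511423–107535478, was at 26.6 ± 7.17 against 125.4 ± 35.6 TPM, and its neighbour Serpinb10 overlaps it on the same strand. The chemokine gene Ppbp was at 29.9 ± 9.80 against 110.9 ± 11.4 TPM, the adaptor gene Blnk at 33.7 ± 5.98 against 112.7 ± 20.3 TPM, the calcium-binding Efhd1 at 3.75 ± 0.537 against 17.8 ± 0.198 TPM, and the sodium-iodide symporter gene Slc5a5 at 38.0 ± 11.2 against 114.2 ± 1.94 TPM. Hddc3 was at 4.47 ± 1.18 against 16.9 ± 2.73 TPM. The histone gene Hist1h2bl (chr13:21715763–21716143) was listed at 0 in both libraries labelled Rank+/+ and at 20.5 and 15.4 TPM in those labelled Rankfl/fl (limma adjusted p = 0.0581). Its limma adjusted p was 0.0429 without the variance trend and 0.152 at a mean of at least 5 TPM. It has near-identical paralogs. Hddc3, Efhd1 and Prss8 overlap genes of the opposite strand, which the sources used here do not say were counted apart.

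The 12 genes given next were lower in both libraries labelled Rankfl/fl, and again none of them passed the threshold. Scgb1a1, the club cell secretory protein (chr19:9083636–9087958), was at 67.3 ± 8.53 TPM (SD, n = 2) in the libraries labelled Rank+/+ and at 11.6 ± 3.58 TPM in those labelled Rankfl/fl, a log2 fold change of −2.47 ± 0.25 (SE; limma adjusted p = 0.173). Cck, which encodes the peptide hormone cholecystokinin, was at 360.6 and 197.1 TPM against 30.1 and 34.9 TPM (log2 fold change −3.00 ± 0.32 SE; limma adjusted p = 0.173). Serpina3i, 1 of the paralogs of Serpina3h and its neighbour at chr12:104263122–104269372, was at 24.9 ± 4.28 against 1.98 ± 0.509 TPM (limma adjusted p = 0.0922). Col6a3, a chain of collagen VI, was at 51.1 ± 5.06 against 18.4 ± 3.19 TPM. Smad6, an inhibitor of BMP signalling, was at 27.0 and 29.6 against 12.4 and 11.6 TPM. Tubb3, a neuronal tubulin, was at 30.9 ± 7.62 against 9.16 ± 1.96 TPM, and Gfra2, a receptor of neurturin, at 26.6 and 16.8 against 4.80 and 5.86 TPM. The urea transporter gene Slc14a1 was at 18.9 ± 4.74 against 4.90 ± 0.651 TPM, the glutaminyl cyclase gene Qpct at 33.9 ± 2.70 against 12.8 ± 2.23 TPM, and the steroid-metabolizing Akr1c18 at 11.3 ± 1.53 against 2.83 ± 0.587 TPM. Raet1d, a ligand of the immune receptor NKG2D, was at 39.4 ± 14.9 against 9.14 ± 0.127 TPM, and Chst1, a sulfotransferase, at 41.0 ± 2.84 against 18.9 ± 1.39 TPM. Raet1d overlaps Raet1e, Tubb3 overlaps Gm20388 and Col6a3 overlaps Gm36970, so reads of these pairs may have been shared.

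**Figure D2:**
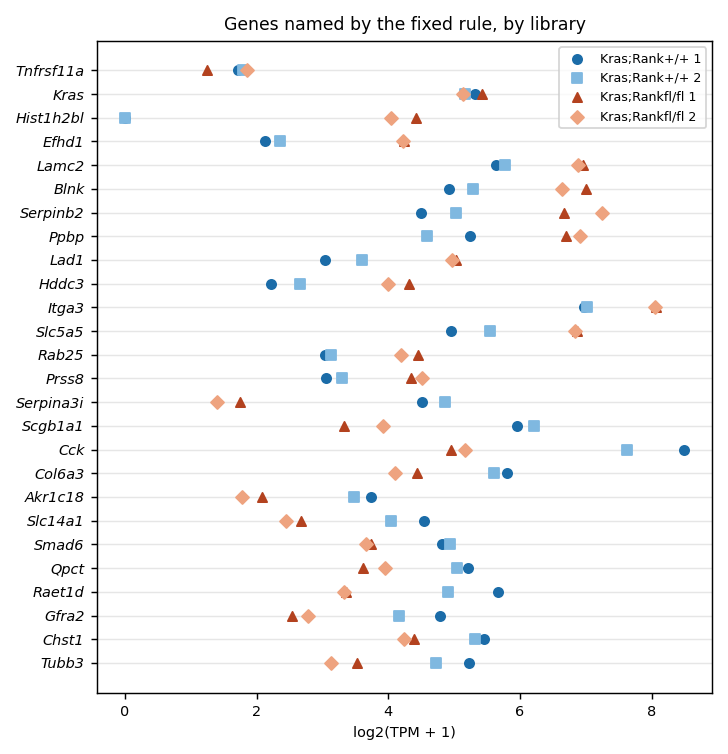
Each row is a gene and each point 1 library, with log2(TPM + 1) on the x axis. Rows from the top are Tnfrsf11a and Kras, whose libraries overlap, then 12 genes higher and 12 lower in the libraries labelled Rankfl/fl, whose 2 libraries lie on 1 side of both libraries labelled Rank+/+ and none of which passed the threshold.

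Cell cycle genes fell in the libraries labelled Rankfl/fl. All 36 tested members had a negative fold change, 32 had both Rankfl/fl values under both Rank+/+ values, and the median log2 fold change was −1.44 (camera adjusted p = 1.37e-17). The adjusted p was 0.824 with an estimated correlation, and the rotation test fry gave an adjusted p of 0.618 (0.231 unadjusted). No member passed on its own, either over all genes or adjusted over the list alone, and 17 were lower at an unadjusted p under 0.05. Rrm2, a subunit of ribonucleotide reductase, was at 145.0 and 30.9 TPM in the libraries labelled Rank+/+ and at 12.8 and 14.4 TPM in those labelled Rankfl/fl. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at 119.4 and 27.2 against 11.03 and 13.97 TPM. Prc1, a regulator of cytokinesis, was at 80.8 and 20.7 against 8.46 and 10.01 TPM, and Ccne1, cyclin E1, at 47.1 and 24.8 against 14.3 and 14.4 TPM. Relative to each gene's mean over the 4 libraries, the list's median was 1.56 in Rank+/+ replicate 1 and −0.07 in Rank+/+ replicate 2, against −0.90 and −0.49 in the libraries labelled Rankfl/fl. The median log2 fold change was −0.62 without Rank+/+ replicate 1 and −2.29 without Rank+/+ replicate 2.

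Genes of translation and of mitochondrial respiration fell as groups, by smaller amounts. Of 81 tested cytosolic ribosomal protein genes, 79 had a negative fold change and 76 had both Rankfl/fl values under both Rank+/+ values, with a median of −0.34 (camera adjusted p = 2.25e-16, and adjusted p = 0.824 with an estimated correlation). Rplp1 was at 5089 and 3522 TPM against 2689 and 2731 TPM, and Rpsa at 1779 and 1206 against 907 and 856 TPM. Many ribosomal protein genes have processed pseudogenes, so single values are uncertain. Of 77 tested nuclear genes of oxidative phosphorylation, 71 had a negative fold change, with a median of −0.24 (camera adjusted p = 2.22e-10, and adjusted p = 0.824 with an estimated correlation). Cox4i1, a subunit of cytochrome c oxidase, was at 936 ± 180 TPM (SD, n = 2) against 739 ± 56.2 TPM, and Ndufa5, a subunit of complex I, at 121.3 ± 14.5 against 78.0 ± 2.34 TPM. Mitochondrial ribosomal protein genes (77 tested, 61 negative, median −0.15, camera adjusted p = 1.82e-05), TCA cycle genes (21 tested, 20 negative, median −0.15, camera adjusted p = 0.00202) and fatty acid oxidation genes (18 tested, 11 negative, median −0.12, camera adjusted p = 0.0255) also passed, each with an adjusted p of 0.824 at an estimated correlation. In these 3 lists Mrpl54 was at 113.5 and 79.5 against 54.1 and 63.3 TPM, the isocitrate dehydrogenase subunit Idh3a at 74.7 and 48.8 against 48.8 and 41.6 TPM, and the carnitine carrier Slc25a20 at 54.1 and 47.0 against 36.1 and 35.7 TPM. No member of these 5 lists passed on its own or adjusted over the list alone. Leaving out Rank+/+ replicate 1 brought the medians to −0.22, −0.10, −0.05, −0.04 and −0.03 in the order given and ended the calls of mitochondrial ribosomal protein (camera adjusted p = 0.0792), TCA cycle and fatty acid oxidation genes (0.214 for each). Leaving out Rank+/+ replicate 2 gave −0.25, −0.24 and −0.21 for these last 3 lists, and fatty acid oxidation was also lost without Rankfl/fl replicate 2 (−0.05; camera adjusted p = 0.0875).

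Glycolysis genes did not move together. Of 17 tested members, 8 had a positive and 9 a negative fold change, with a median of −0.06, a mean of 0.03 and a camera adjusted p of 0.656. The median was 0.02 without Rankfl/fl replicate 2 and 0.00 with quantile normalization, where it had changed sign. Eno1, the glycolytic enolase, was at 1512 and 946 TPM against 776 and 677 TPM, while the hexokinase gene Hk2 was at 59.2 and 89.4 against 105.7 and 92.3 TPM. No member passed adjusted over the list alone.

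NF-kB target genes rose in the libraries labelled Rankfl/fl as a list, with 20 of 27 tested members positive and a median log2 fold change of 0.37 (camera adjusted p = 0.0332). The adjusted p was 0.824 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone, with 6 higher and 0 lower at an unadjusted p under 0.05 in limma. The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 were at 8.23 and 15.7 against 38.2 and 58.5 TPM and at 11.02 and 32.3 against 58.2 and 128.9 TPM. Tnf, the tumour necrosis factor gene, was at 7.33 and 10.6 against 19.7 and 30.3 TPM, and the monocyte chemokine gene Ccl2, at 662 and 920 against 560 and 654 TPM, had the opposite sign. The call was lost without Rank+/+ replicate 1 (median 0.12) and without Rankfl/fl replicate 2 (0.29). Relative to each gene's mean over the 4 libraries, the NF-kB median was lowest in Rank+/+ replicate 1 (−0.28) and highest in Rankfl/fl replicate 2 (0.23). Macrophage markers were lowest and highest in the same libraries (−1.004 and 1.11). Values of whole libraries cannot tell which cells expressed the NF-kB targets. The list of Rank pathway components had 14 of 15 tested members positive and a median of 0.23 (camera adjusted p = 0.0423, and adjusted p = 0.824 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone and 1 higher at an unadjusted p under 0.05 in limma. Tnfrsf11b, the soluble decoy receptor of Rankl, was at 13.8 and 35.3 against 54.0 and 50.0 TPM, and the adaptor gene Traf6 at 9.78 and 11.2 against 14.2 and 14.3 TPM. That call was kept without Rank+/+ replicate 1 (median 0.27; camera adjusted p = 0.0155). It was lost without Rank+/+ replicate 2 (0.27; 0.15), Rankfl/fl replicate 1 (0.29; 0.126) or Rankfl/fl replicate 2 (0.20; 0.122), with median-of-ratios scaling (0.16; 0.0509) and quantile normalization (0.11; 0.0537), and without the variance trend (0.23; 0.0552). ERK pathway output genes, which follow Ras signalling, were not called (17 tested, median −0.03, camera adjusted p = 0.657), and their median was 0.03 without Rank+/+ replicate 1 and 0.07 without Rankfl/fl replicate 2.

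Markers of the transitional alveolar epithelial state, which appears between type II and type I cells in injured lung, rose as a list in the libraries labelled Rankfl/fl. Of 14 tested genes, 10 were positive and 4 negative, 9 were higher adjusted over the list alone and 0 over all genes, and the median log2 fold change was 1.31 (camera adjusted p = 0.000519). The adjusted p was 0.824 with an estimated correlation. The keratin genes Krt8, Krt18 and Krt7 were at 249 ± 105, 344 ± 122.9 and 309 ± 77.1 TPM (SD, n = 2) in the libraries labelled Rank+/+ and at 713 ± 43.1, 940 ± 12.2 and 820 ± 9.98 TPM in those labelled Rankfl/fl. Clu, which encodes clusterin, was at 306 and 819 against 2563 and 2045 TPM. Cdkn1a, a cell cycle inhibitor on the same list, was at 1081 and 789 against 1001 and 821 TPM. Over the leave-one-out fits the median ran from 0.98 to 1.69. General epithelial genes were higher as well, with 37 of 37 positive and a median of 1.02 in a list written after these results, so the keratins do not set this state apart from more epithelial transcripts overall.

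Alveolar type II markers did not move as a group (11 tested, median 0.30, camera adjusted p = 0.623), and their members went both ways. Adjusted over the list alone, the surfactant protein gene Sftpb fell (22.3 and 16.1 against 8.50 and 6.76 TPM) and the mucin gene Muc1 rose (2.01 and 5.88 against 15.3 and 15.3 TPM), with 0 members past the threshold over all genes. Sftpc, a surfactant protein gene of type II cells, was at 35.0 and 7.97 TPM against 2.94 and 3.95 TPM, and Sftpd was at 9.05 and 9.01 against 12.8 and 13.9 TPM. These are low levels beside those of mesenchymal and myeloid transcripts in the same libraries, where Col1a1 ran from 2031 to 3415 TPM and Lyz2 from 2937 to 15408 TPM. Of 15 alveolar type I markers (median 0.18, camera adjusted p = 0.726), Gprc5a and Col4a3 rose and Sema3a fell adjusted over the list alone. Gprc5a was at 139.2 ± 3.68 TPM (SD, n = 2) against 250.5 ± 1.51 TPM, and the median was −0.01 without Rank+/+ replicate 1. Club cell markers fell (7 tested, 6 negative, median −0.74, camera adjusted p = 0.00746, and adjusted p = 0.824 with an estimated correlation), with Scgb1a1 the 1 gene that passed adjusted over the list alone. Cyp2f2, a cytochrome P450 of club cells, was at 9.31 and 7.33 against 5.68 and 3.62 TPM. The club cell call was lost without Rank+/+ replicate 2 (−0.35; camera adjusted p = 0.462) and with no filter on low values (−0.03; 0.229), and the median was −1.21 without Rank+/+ replicate 1. Ciliated cell markers were not called (11 tested, median 0.70, camera adjusted p = 0.0885), but they were without Rank+/+ replicate 2 (1.30; 0.000883) or Rankfl/fl replicate 1 (1.05; 0.0177), with median-of-ratios scaling (0.66; 0.0418), with quantile normalization (0.60; 0.0452) and with no filter on low values (0.53; 0.0398). Their median was 0.14 (camera adjusted p = 0.812) without Rank+/+ replicate 1. Basal and progenitor-associated genes were not called either (15 tested, median −0.03, camera adjusted p = 0.656), and their median was 0.01 with quantile normalization, 0.03 without Rankfl/fl replicate 1 and 0.04 without Rankfl/fl replicate 2. Among them the basal keratin gene Krt5 was at 10.5 and 2.92 against 0.91 and 0.81 TPM, and Ly6a, which encodes Sca-1, at 277 and 316 against 456 and 442 TPM.

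Markers of other cell types also differed between the genotype labels. Macrophage markers were higher in the mean of the libraries labelled Rankfl/fl (23 tested, 21 positive, median 0.95, camera adjusted p = 0.000444, and adjusted p = 0.824 with an estimated correlation). Only 9 of the 23 had both Rankfl/fl values above both Rank+/+ values. The alveolar macrophage genes Marco and Chil3 were at 3.26 and 41.0 against 149.2 and 328.8 TPM and at 2.33 and 35.7 against 77.1 and 135.5 TPM. Those 2 genes are among the 9, while the abundant members Ctss (355 and 694 against 520 and 1278 TPM) and Tyrobp (166 and 334 against 301 and 659 TPM) overlapped. Relative to each gene's mean over the 4 libraries, the macrophage median was −1.004 in Rank+/+ replicate 1 and 1.11 in Rankfl/fl replicate 2. It was 0.01 in Rank+/+ replicate 2 and −0.16 in Rankfl/fl replicate 1, so the list was not higher in both libraries labelled Rankfl/fl. That call was lost without Rank+/+ replicate 1 (0.50; camera adjusted p = 0.0704) or Rankfl/fl replicate 2 (0.32; 0.52), and the median was 1.60 without Rankfl/fl replicate 1. Neutrophil markers rose as well (9 tested, 7 positive, median 0.82, camera adjusted p = 0.0489, and adjusted p = 0.824 with an estimated correlation), among them Mmp9, which encodes a gelatinase, at 3.19 and 55.0 against 106.4 and 113.1 TPM. It was not called without Rank+/+ replicate 1 (0.48; camera adjusted p = 0.0704) or Rankfl/fl replicate 2 (0.68; 0.596), with a pseudocount of 0.1 (0.96; 0.0627) or with no filter (0.80; 0.121). No macrophage or neutrophil marker passed adjusted over its list alone. Endothelial markers fell (20 tested, 19 negative, median −0.83, camera adjusted p = 3.82e-07, and adjusted p = 0.824 with an estimated correlation), with 4 lower and 1 higher adjusted over the list alone. The vascular endothelial growth factor receptor gene Flt1 was at 16.4 and 22.6 against 7.93 and 5.79 TPM and the transcription factor gene Sox18 at 24.0 and 51.3 against 11.1 and 7.91 TPM, whereas the carbonic anhydrase gene Car4 rose, at 1.72 and 13.6 against 56.0 and 67.97 TPM. Without Rank+/+ replicate 2 the endothelial median was −0.20 (camera adjusted p = 0.198), and without Rank+/+ replicate 1 it was −1.53.

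**Figure D3:**
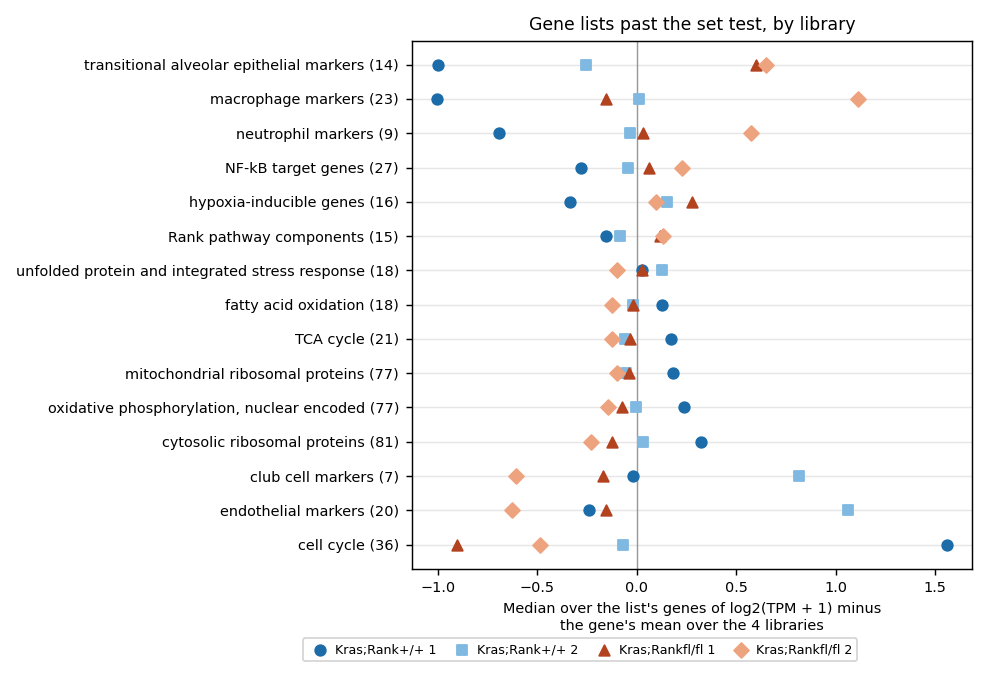
Each row is a gene list that passed the set test, with its number of tested genes in parentheses, and each point is 1 library. The x axis is the median over the list of log2(TPM + 1) minus the gene's mean over the 4 libraries, which for cell cycle genes is 1.56 and −0.07 in the libraries labelled Rank+/+ and −0.90 and −0.49 in those labelled Rankfl/fl. No list passed with an estimated correlation or in the rotation test fry.

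Fibroblast and smooth muscle markers were not called (24 tested, median 0.16, camera adjusted p = 0.429), and the test pointed down while the median and the mean of 0.08 were positive. Adjusted over the list alone, Col6a3, Thy1 and Des fell, with Thy1 at 277 and 180 against 98.8 and 66.1 TPM and Des, the desmin gene of muscle, at 128.5 and 78.3 against 42.3 and 40.8 TPM. The list was lower without Rank+/+ replicate 1 (−0.14; camera adjusted p = 0.00177) and without Rankfl/fl replicate 1 (−0.19; 0.00973). Mesothelial markers were not called (5 tested, median −0.72, camera adjusted p = 0.228), with a median of −0.08 without Rank+/+ replicate 1 and −1.35 without Rank+/+ replicate 2, and Msln, which encodes mesothelin, rose adjusted over the list alone (142.5 ± 44.4 TPM against 387.8 ± 1.24 TPM, SD, n = 2). T and NK cell, B cell and erythroid markers had 2, 4 and 1 tested genes, too few for the set test, and 0 of these genes passed adjusted over their lists alone.

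Hypoxia-inducible genes rose, with 16 of 16 tested members positive and a median of 0.35 (camera adjusted p = 0.0223, and adjusted p = 0.824 with an estimated correlation). Vegfa, the vascular endothelial growth factor gene, was at 246 and 800 against 1157 and 1086 TPM, and Adm, the adrenomedullin gene, at 478 and 968 against 1146 and 910 TPM. The call was lost without Rank+/+ replicate 1 (0.14; camera adjusted p = 0.355) or Rankfl/fl replicate 1 (0.30; 0.203). The list of the unfolded protein and integrated stress response fell slightly (18 tested, 13 negative, median −0.07, camera adjusted p = 0.0423, and adjusted p = 0.824 with an estimated correlation). Its members with the smallest p were the serine and glycine synthesis genes Psat1, at 206 and 134 against 96.7 and 68.5 TPM, and Shmt2, at 97.8 and 85.3 against 71.5 and 57.8 TPM. It was not called without Rank+/+ replicate 2 (−0.04; camera adjusted p = 0.275), without Rankfl/fl replicate 2 (−0.02; 0.26) or with quantile normalization (−0.06; 0.369), and the median was −0.17 without Rank+/+ replicate 1 and −0.16 without Rankfl/fl replicate 1. No member of these 2 lists passed on its own or adjusted over the list alone.

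MHC class II genes were not called, with 6 of 6 tested members positive and a median of 0.67 (camera adjusted p = 0.0558). H2-Ab1 was at 23.8 and 50.6 against 73.7 and 68.8 TPM. The list passed with median-of-ratios scaling (0.61; camera adjusted p = 0.0418), with quantile normalization (0.54; 0.0432) and with no filter (0.50; 0.0167), and also without Rank+/+ replicate 2 (1.14; 0.0184) or Rankfl/fl replicate 1 (0.88; 0.00507). Its median was 0.35 (camera adjusted p = 0.237) without Rank+/+ replicate 1 and 0.32 (0.478) without Rankfl/fl replicate 2. Interferon-stimulated genes (26 tested, median 0.22, camera adjusted p = 0.179) passed without Rank+/+ replicate 2 (0.28; 0.0404) or Rankfl/fl replicate 1 (0.38; 0.000795), with 0.07 (0.745) without Rank+/+ replicate 1 and 0.02 (0.52) without Rankfl/fl replicate 2. MHC class I genes (11 tested, median 0.12, camera adjusted p = 0.566) passed without Rankfl/fl replicate 1 (0.51; 0.00491), with −0.09 without Rankfl/fl replicate 2. Cholesterol synthesis (24 tested, median 0.16, camera adjusted p = 0.133) passed without Rank+/+ replicate 2 (0.26; 0.0128), with 0.02 (0.812) without Rank+/+ replicate 1. The p53 target genes (18 tested, median −0.10, camera adjusted p = 0.429) passed without Rank+/+ replicate 2 too, at −0.31 (0.0184), and their median was 0.11 without Rank+/+ replicate 1 and 0.04 without Rankfl/fl replicate 2. Immediate early genes (21 tested, median 0.08, camera adjusted p = 0.795) had a median of −0.06 without Rankfl/fl replicate 1. NRF2 target genes (16 tested, median 0.03, camera adjusted p = 0.528) and genes of fatty acid and surfactant lipid synthesis (19 tested, median 0.04, camera adjusted p = 0.623) changed sign with median-of-ratios scaling, to −0.04 and −0.03. In the last 3 lists the test pointed down, against a positive median. For replication-dependent histone genes (39 tested, median 0.02, camera adjusted p = 0.657) the median changed sign with median-of-ratios scaling (−0.02) and quantile normalization (−0.08). They were higher without Rank+/+ replicate 1 (0.34; camera adjusted p = 0.0222) or Rankfl/fl replicate 1 (0.46; 4.26e-05) and lower without Rankfl/fl replicate 2 (−0.34; 0.00915). Adjusted over the list alone, 4 histone genes were higher, among them Hist1h2bl, and most histone messages lack the poly-A tail on which the RNA was selected.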

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

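Leaving out genes named as microRNAs or small nucleolar RNAs was the alternative chosen after seeing the data. Limma called 1 gene higher and 1 lower in the libraries labelled Rankfl/fl. It called 0 higher and 1 lower with a pseudocount of 0.1 or a mean of at least 5 TPM, 0 and 0 with no filter (1152 and 583 at an unadjusted p under 0.05), 4 and 3 without the variance trend, and 1 and 1 with either scaling or without the short RNA genes, where 1 of the 2 genes was shared. With the replicate block it called 0 and 0 (1109 and 532 at an unadjusted p under 0.05; adjusted p = 0.187 for Serpina3h and 0.37 for Mir3098, with unchanged log2 fold changes of −6.06 and 4.36). The labels do not say what same-numbered libraries share. Across genes, deviations of same-numbered libraries from their group means correlated at 0.0764. This compares only 1 deviation per group and includes Rank+/+ replicate 1, which stood apart, so it cannot exclude a shared batch or preparation. The block leaves fewer residual degrees of freedom. It changed the call of 0 primary lists and brought MHC class II and ciliated markers past the threshold (camera adjusted p = 0.0143 for each). Over the fits with 1 library left out, 0 to 116 genes were higher and 0 to 93 lower, and 7 to 14 of the other lists were called, against 10. Without Rank+/+ replicate 2, the only Rank+/+ library left was replicate 1, which stood apart from the others. The spread in that fit came from the 2 Rankfl/fl libraries alone, the pair with the smallest median absolute log2 difference (0.184). The rise in calls there therefore cannot be read as an effect of genotype. With an estimated correlation, 0 of the other lists and none of the 5 called primary lists passed (medians −0.24 for oxidative phosphorylation, −0.15 for the TCA cycle, −0.12 for fatty acid oxidation, 0.37 for NF-kB targets and −1.44 for cell cycle). Correlation between genes cannot account for this in every list. The transitional and Rank pathway lists had estimates of −0.02 and −0.05, below the preset 0.01. Their unadjusted camera p still rose, from 0.000113 to 0.0546 and from 0.0185 to 0.128. Most other called lists had estimates far above the preset value, such as 0.971 for cell cycle genes, 0.847 for macrophage and 0.793 for endothelial markers. There, correlation and the fewer degrees of freedom cannot be told apart. The rotation test fry, which is not among the alternatives, passed no list either. Under the remaining alternatives, left-out libraries apart, the 5 called primary lists kept their direction and their call, and alveolar type II markers stayed uncalled. Adjusted p over all alternatives ran from 1.6e-11, 0.000439, 0.0124, 0.00104 and 1.61e-24, in the same order, to 0.824, and from 0.631 to 0.968 for Tnfrsf11a. For Serpina3h it ran from 0.0125 to 0.968 and for Mir3098 from 0.0208 to 0.968. Both lost their calls with no filter (−6.06 and 4.36; 0.149 for each), and Mir3098 also with a pseudocount of 0.1 (7.62; 0.0745) and a mean of at least 5 TPM (4.36; 0.146), so that p moved past the threshold without a smaller fold change.

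Signs reversed, all in results that were not called and with a cause that was not tested, for Kras (−0.03 with median-of-ratios scaling, −0.02 with quantile normalization), NRF2 targets (−0.04 with median-of-ratios scaling), lipid synthesis (−0.03 with either scaling), basal genes (0.16 at a mean of at least 5 TPM, 0.01 with quantile normalization), histones (−0.03 at a mean of at least 5 TPM, −0.02 with median-of-ratios scaling, −0.08 with quantile normalization) and glycolysis (0.00, above 0 before rounding, with quantile normalization). With 1 library left out, values ran from −0.36 to −0.10 for oxidative phosphorylation, −0.24 to −0.04 for the TCA cycle, −0.21 to −0.03 for fatty acid oxidation, 0.12 to 0.43 for NF-kB targets, −2.29 to −0.62 for cell cycle, 0.24 to 0.35 for alveolar type II markers, −0.14 to 0.02 for glycolysis and −0.50 to 0.10 for Tnfrsf11a. They ran from −0.10 to 0.19 for Kras, −0.11 to 0.07 for ERK output, −0.09 to 0.51 for MHC class I, −0.07 to 0.10 for NRF2 targets, −0.01 to 0.30 for type I markers, −0.02 to 0.04 for basal genes, −0.08 to 0.04 for lipid synthesis, −0.19 to 0.35 for fibroblast markers, −0.06 to 0.12 for immediate early genes, −0.31 to 0.11 for p53 targets and −0.34 to 0.46 for histones. At a mean of at least 5 TPM, the club cell, mesothelial and MHC class II lists had too few members for a value. Depth is unknown, so what it limits could not be measured.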

Other observations

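The tests and bounds for Rank+/+ replicate 1 and for macrophages in the cell cycle, respiration and ribosomal lists, and the test of the genes around Tnfrsf11a, were chosen only after those results had been seen. A list of 38 epithelial junction and identity genes was written after the values of the keratins, Epcam and Cdh1 had been seen to be higher, and before its own members were looked at. Of its 37 tested genes, 37 had a positive fold change in the libraries labelled Rankfl/fl, 23 were higher adjusted over the list alone and 0 over all genes. The median log2 fold change was 1.02 (interquartile range 0.62 to 1.37, camera adjusted p = 3.13e-17, and adjusted p = 0.802 with an estimated correlation). Ocln, the tight junction protein occludin, was at 5.05 and 12.2 TPM against 28.4 and 26.04 TPM, and Esrp1, an epithelial splicing factor, at 3.12 and 7.04 against 21.6 and 18.1 TPM. The desmosomal gene Dsp was at 7.42 and 6.34 against 13.4 and 16.7 TPM, and the protease inhibitor gene Spint2 at 63.7 and 193.5 against 425 and 402 TPM. The adhesion genes Epcam and Cdh1, left out of the list and named after their values were seen, were at 31.8 and 90.8 against 261.9 and 205.1 TPM and at 21.6 and 54.6 against 180.2 and 159.4 TPM.

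Other members of the Serpina3 family were lower in the libraries labelled Rankfl/fl too. Serpina3g was at 65.3 and 49.5 TPM against 18.5 and 10.7 TPM, Serpina3n at 84.7 and 56.9 against 44.3 and 23.4 TPM, and Serpina3f at 9.13 and 8.35 against 0.21 and 0.32 TPM. Serpina3k was at 4.12 and 4.34 TPM in the libraries labelled Rank+/+ and listed at 0 in both labelled Rankfl/fl. The family's summed TPM was 296 and 300.2 against 66.85 and 37.7.

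Epithelial genes were higher while Sftpc, Sftpb and Scgb1a1 were lower in the libraries labelled Rankfl/fl. Rank+/+ replicate 1 alone is argued against as the reason for the first part. The Rankfl/fl mean exceeded Rank+/+ replicate 2 by a median of 0.80 over the list, more than the gap of 0.49 between the Rank+/+ libraries. That comparison has only 1 Rank+/+ library, whose own departure cannot be estimated. A smaller share of epithelial cells as a whole would lower general epithelial genes as well, at an unchanged level per cell, but 37 of 37 had a positive fold change. This goes only weakly against that reason for the second part. The list was written after genes of its kind had been seen to be higher, and its members vary together (estimated correlation 0.436). These general genes cannot test the share of type II or club cells alone. Of the tested type II markers 8 of 11 were positive, and of the club cell markers 6 of 7 were negative. A larger share of epithelial cells in these libraries is a candidate explanation for the first part. The list's median of 1.02 lay above the 0.5 set beforehand. The list was, however, written after the keratins, Epcam and Cdh1 had been seen to be higher, so this result lends little independent support. Values of whole libraries, which also hold many mesenchymal and myeloid transcripts, cannot separate a share of cells from the level per cell. An effect of the Rank genotype on either remains open and untested.

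Cell cycle, oxidative phosphorylation and cytosolic ribosomal protein genes were lower together, and Rank+/+ replicate 1 held their highest levels. Without it the medians were −0.62, −0.10 and −0.22, beyond the gaps between the libraries labelled Rankfl/fl (0.29, −0.06 and −0.09) but within those between the libraries labelled Rank+/+ (−1.66, −0.26 and −0.28), which that library itself widens. Rank+/+ replicate 2 lay above both Rankfl/fl libraries in 32 of 36, 54 of 77 and 76 of 81 genes, and the lists stayed called by camera (adjusted p = 1.11e-16, 1.87e-05 and 2.69e-12), but with a preset correlation of 0.01 against estimates of 0.971, 0.58 and 0.715 over all 4 libraries and with 1 Rank+/+ library left, so that library's departure and a difference between genotypes cannot be told apart. Dilution by macrophages would lower cell cycle genes and fibroblast and smooth muscle markers alike. With all libraries the markers' median was 0.16 (SD 0.78 over members) against −1.44, which argues against dilution as the whole cause. Of the 24 markers 15 were positive, while Col6a3, Thy1 and Des fell by −1.43, −1.45 and −1.25. Without Rank+/+ replicate 1 the medians were −0.14 (SD 0.46) and −0.62. That margin was narrow, and an SD over members is not an error of the median, so dilution stays undecided without that library. A difference in growth between cultures and an effect of genotype remain open and untested.

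Serpina3h and Serpina3i were lower in both libraries labelled Rankfl/fl. Reads moved to a paralog are argued against, because the family's sum in the higher of these libraries, 66.85 TPM, lay far under both Rank+/+ sums. A linked chromosome segment of another strain might also lower neighbouring genes. Within 2 Mb, leaving out the family, 3 of 31 tested genes had an unadjusted p under 0.05 (9.68%, exact 95% confidence interval 2.04% to 25.8%) against 1380 of 13926 elsewhere (one-sided Fisher's exact p = 0.605), an interval too wide to decide. An effect of genotype remains open and untested.

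Within 10 Mb of Tnfrsf11a, 4 of 18 tested genes had an unadjusted p under 0.05 (Serpinb2, Serpinb10, Serpinb8 and Gm20753), against 1385 of 13944 elsewhere (one-sided Fisher's exact p = 0.0966). This asked whether a chromosome segment from the floxed allele's strain of origin was present, and it cannot decide that. Serpinb2 had been seen among the genes of smallest p before the window was chosen. Serpinb10 overlaps it on the same strand, so the 2 are not independent. Of 1183 microRNA genes in the files, 22 were above 0 in both libraries labelled Rankfl/fl and in neither labelled Rank+/+, and 6 the other way round, while the 4 other pairs of libraries gave 2, 13, 8 and 12. The other 2 splits of the libraries into pairs called 0 and 0 genes in limma, with 229 and 221 at an unadjusted p under 0.05 against 1454 for the genotype labels. Each of these splits groups Rank+/+ replicate 1, which stood apart, with a library labelled Rankfl/fl. Its departure then widens the spread within groups and lowers these counts, so they are no baseline for the genotype labels. So few splits also cannot give a share under 0.05.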
